A study of Mus musculus with 6 samples.

How the data were processed

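The series measured messenger RNA by sequencing in mouse hematopoietic stem cells (HSCs), sorted from the lineage-negative, Sca-1-positive, c-Kit-positive (LSK) compartment as cells without CD48 and with CD150. There were 3 control samples (Emp1fl/fl, mice with floxed Emp1 alleles) and 3 Emp1-deficient samples (Emp1fl/fl,Tie2-Cre, in which the Cre recombinase is driven by the Tie2 promoter, active in endothelial and blood-forming cells). Per the labels' protocols, total RNA was extracted with a miRNeasy kit, reverse-transcribed and amplified by Geo-seq, a method for low input, and made into libraries with the transposase-based TruePrep V2 kit. Samples were grouped by the genotype in the labels. The labels do not say whether replicates came from separate mice, so p-values measure only the spread between these samples, which may be technical.

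The values used were the authors' deposited FPKM (fragments per transcript length and per library size), with 2 decimals, for 55401 Ensembl gene identifiers in 6 libraries. Per the submitters' processing notes, Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq and DESeq2 were used with the mouse build mm10. The notes as used here give no role or order for these tools, so which of them made the FPKM values, and with which settings, is not given in the sources used here. FPKM values are relative to each library's own total, so a transcript that takes a larger share lowers all others. Amplification from low input adds scatter that FPKM values do not show, and reads shared by near-identical genes can be split or dropped.

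Gene symbols, biotypes, positions, exonic length and GC content came from GENCODE release M21 on GRCm38, the assembly that mm10 denotes. Of the identifiers, 55141 matched and 260 did not. Another 107 identifiers shared a symbol with a second one, and the symbol was kept on the identifier with the highest mean. No protein-coding gene above 100 FPKM in any library was listed at 0 in another, so means with standard deviations were used, while no fold is given for a gene listed at 0 throughout a genotype.

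Read counts were not used. Relative depth was estimated from low single-exon genes (600 to 1500 bp, under 0.5 FPKM in both libraries compared), as the most frequent ratio of FPKM between the reference and each other library. This takes such genes to hold equal fragment numbers in both libraries, which was not tested. The estimate rested on 994 to 1371 genes in each library other than the reference, control replicate 1. Set to 1 for that library, it was 0.774 and 1.02 for control replicates 2 and 3, and 0.774, 0.959 and 1.88 for Emp1-deficient replicates 1, 2 and 3. Absolute depth stays unknown, so no counting intervals or detection floors are given. A value near 0 is therefore least certain in the shallower libraries.

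Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested (15723 genes), with Emp1 kept whatever the filter. Differences were fitted on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust, two-sided), with genotype as the only term and 4 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 was the threshold. A log2 fold change on this scale understates the change of genes near or below 1 FPKM.

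Gene lists of pathways and of markers of other cell types were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists that had at least 5 tested members. Beside it stand camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes. Differences of library measures were tested by exact two-sided permutation, for which 3 against 3 cannot give a p below 0.1.

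The groups, the tests, the gene lists, the alternative settings and the rule for named genes were fixed before the data were examined. The rule took Emp1 with Emp2, Emp3 and Pmp22; per direction, the 12 largest changes with adjusted p under 0.05, a mean of at least 5 FPKM in the higher genotype, no overlap between genotypes and an established symbol; up to 4 members of each pathway list with the smallest p; and, of each cell type list, up to 3 of the highest members and 2 with the smallest p. It named 165 genes, of which part are printed. Which part was settled after their values had been seen. Genes printed outside the rule are said to be so.

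The steps were tested on simulated data for this comparison. In 20 simulations with 15723 genes and 200 of them changed (drawn from genes with a mean log2 value of at least 2.5, so lower genes were not tested this way), 89.6% of the genes changed by a log2 of 1 and 97.3% of those changed by a log2 of 2 were found. Among calls, 6.16% were false, and fitted changes followed the true ones with a slope of 0.999. A list shifted by a log2 of -0.4 was called in 20 of 20 simulations with the preset correlation, in 19 with an estimated one and in 20 by fry, while 0 of 680 tests of unshifted lists gave a call. The simulated noise was independent between genes, so it does not test the preset correlation.

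The alternative settings chosen beforehand were pseudocounts of 0.1 and 5, no filter, a filter on a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, rescaling to TPM, eBayes without trend and robustness, array weights, a replicate block, the other list tests, and leaving out each library in turn. Removal of each library's trend with GC content and exonic length, and a restriction to protein-coding genes with at least 400 bp of exons, were added after the data had been seen. No gene-count model was run, since whole reads could not be recovered from FPKM. Annotation was read with Python 3.11.15 and pandas 2.3.3, results were tabulated in R with the data.table package (version 1.17.8), and plots were drawn with matplotlib 3.10.9.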

Results

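RNA was profiled in sorted HSCs of 3 control (Emp1fl/fl) and 3 Emp1-deficient (Emp1fl/fl,Tie2-Cre) samples. Between 14334 and 18048 genes per library reached 1 FPKM, and log2 values correlated at r = 0.961 to 0.963 across genes between controls and at 0.956 to 0.969 between Emp1-deficient libraries (genes are not independent replicates). Pairs across genotypes correlated at 0.948 to 0.963, so libraries were not clearly closer within a genotype than across. Relative depth ran from 0.774 to 1.88, with Emp1-deficient replicate 3 the deepest by this estimate, although it had the fewest genes at 1 FPKM (14334). That library also had the lowest share of FPKM in cytosolic ribosomal protein genes (9.36%, against 11.1% to 12.98% in the 5 others) and the highest share in mitochondrially encoded genes (6.78%). The mitochondrial share was 4.12% ± 0.399 in controls and 5.77% ± 0.887 in Emp1-deficient libraries (SD, n = 3 each; exact permutation p = 0.1, the smallest that 3 against 3 allows). The ribosomal protein share was 12.5% ± 0.647 and 11.0% ± 1.54 (exact permutation p = 0.2). The 10 most abundant genes took 8.53% ± 0.291 and 9.39% ± 0.462 of FPKM (exact permutation p = 0.1), and an rRNA-like transcript averaged 16160 ± 3550 and 8967 ± 4140 FPKM, lowest in Emp1-deficient replicate 3 (exact permutation p = 0.2).

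The comparison asked how loss of Emp1, a tetraspan membrane protein of the PMP22 family, altered the transcriptome of HSCs, and the series title names endoplasmic reticulum (ER) stress. Emp1 (ENSMUSG00000030208, mm10 chromosome 6, 135362545 to 135383173) stood at 3.25, 2.64 and 4.32 FPKM in the controls and at 0.58, 0.70 and 0.27 FPKM in the Emp1-deficient libraries. The mean was 84.8% lower, and each Emp1-deficient value lay below each control value, in the direction the genotype labels give. On the log2(FPKM + 1) scale the difference was -1.53 (SE 0.25), with a limma adjusted p of 0.0577 that missed the threshold. It passed with array weights (adjusted p = 0.0456) and among protein-coding genes with at least 400 bp of exons (adjusted p = 0.0185), over alternatives that ranged from 0.0185 to 0.386. The difference was -2.55 with a pseudocount of 0.1 and -0.60 with one of 5. The labels do not say which exons are floxed, so the FPKM of the whole gene may include exons outside the deleted part. Its relatives did not pass the test: Emp3 averaged 350.3 FPKM in controls and 359 FPKM in Emp1-deficient HSCs, Pmp22 1.22 and 1.08 FPKM, and Emp2 0.98 and 0.967 FPKM.

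**Figure D1:**
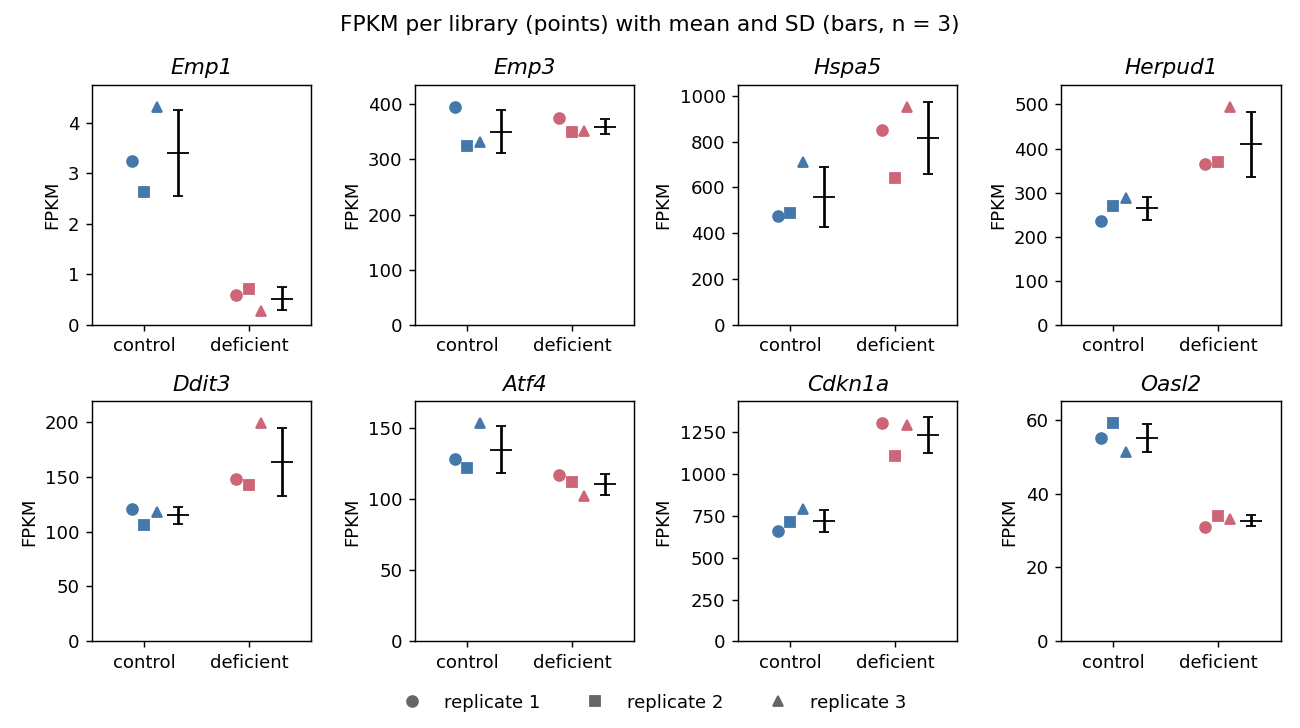
FPKM (vertical axes, starting at 0) of 8 genes in each of the 3 control (blue) and 3 Emp1-deficient (red) libraries; marker shapes give the replicate, and black bars the mean and SD. Emp1 lay between 2.64 and 4.32 in controls and between 0.27 and 0.70 in Emp1-deficient libraries, while Cdkn1a averaged 720.2 and 1236 FPKM.

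In Emp1-deficient HSCs 25 genes rose and 17 fell among 15723 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The largest rises of established genes included Mid1, a microtubule-associated ubiquitin ligase, Plscr2 of the phospholipid scramblase family, and 4 immunoglobulin variable segments. Mid1 (chromosome X, 169685199 to 170005736) rose from 2.39 ± 0.618 to 18.3 ± 6.5 FPKM (SD, n = 3 each; log2 fold change 2.46, SE 0.27, adjusted p = 0.0195), and by 1.62 with a pseudocount of 5. The gene spans the pseudoautosomal boundary, beyond which X and Y share sequence, so the assignment of part of its reads is uncertain. Gm47283 on chromosome Y (90784738 to 90816464), named after its values were seen, averaged 68.2 ± 20.5 and 124 ± 42.5 FPKM and did not pass (adjusted p = 0.312). Plscr2 (chromosome 9, 92275602 to 92297752) rose from 4.15 ± 0.631 to 16.6 ± 3.35 FPKM (1.76, SE 0.18, adjusted p = 0.0129). Clca3a1, of the calcium-activated chloride channel regulator family, rose by 1.40 on the log2 scale, and Mir155hg, the host transcript of a microRNA with roles in immune cells, by 1.14. Arl5b, a small GTPase of the trans-Golgi, rose by 1.05, and Gak, a kinase that acts in the uncoating of clathrin vesicles, by 0.96. A pair of extracellular matrix genes rose as well, Emilin2 from 23.7 ± 5.36 to 48.1 ± 1.71 FPKM and Ecm1 from 12.6 ± 1.71 to 24.0 ± 1.47 FPKM. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 720.2 ± 65.8 to 1236 ± 108.5 FPKM (0.78, SE 0.12, adjusted p = 0.0488). Klf13, a zinc-finger transcription factor named after its value was seen, rose by 0.69.

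Among immunoglobulin segments, Igkv1-110 was listed at 0 in all 3 controls and stood at 8.99, 13.44 and 40.92 FPKM in the Emp1-deficient libraries. Igkv1-117 rose by 3.33 on the log2 scale, Ighv3-6 by 2.52 and Ighv14-3 by 2.29, values that depend on the pseudocount (1.80, 1.14 and 0.92 with one of 5, with no call). Such segments belong to families of near-identical copies, so the assignment of their reads is uncertain. The constant region genes Igkc, Ighm, Ighg2b and Ighg2c did not pass the test. Igkc averaged 314 ± 242 FPKM in controls and 883 ± 544 in Emp1-deficient libraries, and Ighm 89.5 ± 110.5 and 7.96 ± 3.22 (SD, n = 3 each). Ighg2b and Ighg2c, named after their values were seen, did not overlap between the genotypes. Ighg2b stood at 15.68, 1.37 and 15.01 FPKM in controls and at 558, 46.62 and 788 FPKM in Emp1-deficient libraries (adjusted p = 0.249), and Ighg2c at 15.79, 1.26 and 10.86 FPKM and at 435, 49.93 and 105 FPKM (adjusted p = 0.242).

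Among the genes that fell, Hist1h1c (chromosome 13, 23738808 to 23740367), which encodes a linker histone, had the smallest adjusted p of any protein-coding gene. It fell from 131 ± 2.74 to 64.7 ± 2.52 FPKM (log2 fold change -1.004, SE 0.09, adjusted p = 0.00535), and kept its call in 16 of 18 alternatives. The core histone gene Hist1h2bg, named after its value was seen, fell by 0.69 on the log2 scale. The non-classical class I major histocompatibility genes H2-Q7 and H2-Q6 fell from 287 ± 24.5 to 153 ± 19.9 FPKM and from 198 ± 11.9 to 109.5 ± 7.14 FPKM. These are near-identical copies, so how their reads were divided between them is uncertain. Atp2a3, a pump that moves calcium into the ER, fell from 98.9 ± 12.8 to 55.8 ± 3.64 FPKM (-0.81, SE 0.11, adjusted p = 0.0411). Cish, a cytokine-induced inhibitor of STAT5 signalling, also fell by 0.81 on the log2 scale. The cytoskeletal adaptor Obsl1 fell by 1.24, the transmembrane gene Plxdc2 by 1.05, Mtrr, which reactivates methionine synthase, by 0.95, the zinc-finger gene Zfp219 by 0.93, the Groucho-family corepressor Tle2 by 0.91 and Nsmf by 0.77. Vars, the cytosolic valyl-tRNA synthetase, fell from 134 ± 11.4 to 79.0 ± 5.96 FPKM. Of the 20 tested aminoacyl-tRNA synthetases, Vars was the 1 that fell, over all genes and adjusted over the list alone, and 0 rose by limma (3 higher and 1 lower at an unadjusted p under 0.05). Lars, Tars and Nars stood 0.32, 0.31 and 0.37 higher without passing, and the list as a whole was not called (adjusted p = 0.452).

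Of the 42 genes, 27 were protein-coding (12 higher, 15 lower), and 8, mostly short (median exonic length 124 bp, against 3593 bp of all tested genes), were listed at 0 throughout a genotype. At an unadjusted p under 0.05 there were 1022 genes higher and 1529 lower, and in 22.1% of tested genes the genotypes did not overlap, against 10% by chance. After rescaling to TPM, 11 genes were higher and 13 lower, and among protein-coding genes with at least 400 bp of exons 70 were higher and 142 lower. The counts moved with each library left out: 3 higher and 1 lower without control replicate 1, 3 and 0 without control replicate 2, 12 and 4 without control replicate 3, 8 and 16 without Emp1-deficient replicate 1, 1 and 4 without replicate 2, and 1 and 5 without replicate 3. The 24 named genes kept their direction in every alternative in which they were tested, while their calls were kept in 2 to 16 of them. The kept direction is no separate support, because these genes were chosen for having no overlap between the genotypes. With no overlap, leaving out a library or changing the pseudocount or the filter cannot turn the direction.

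**Figure D2:**
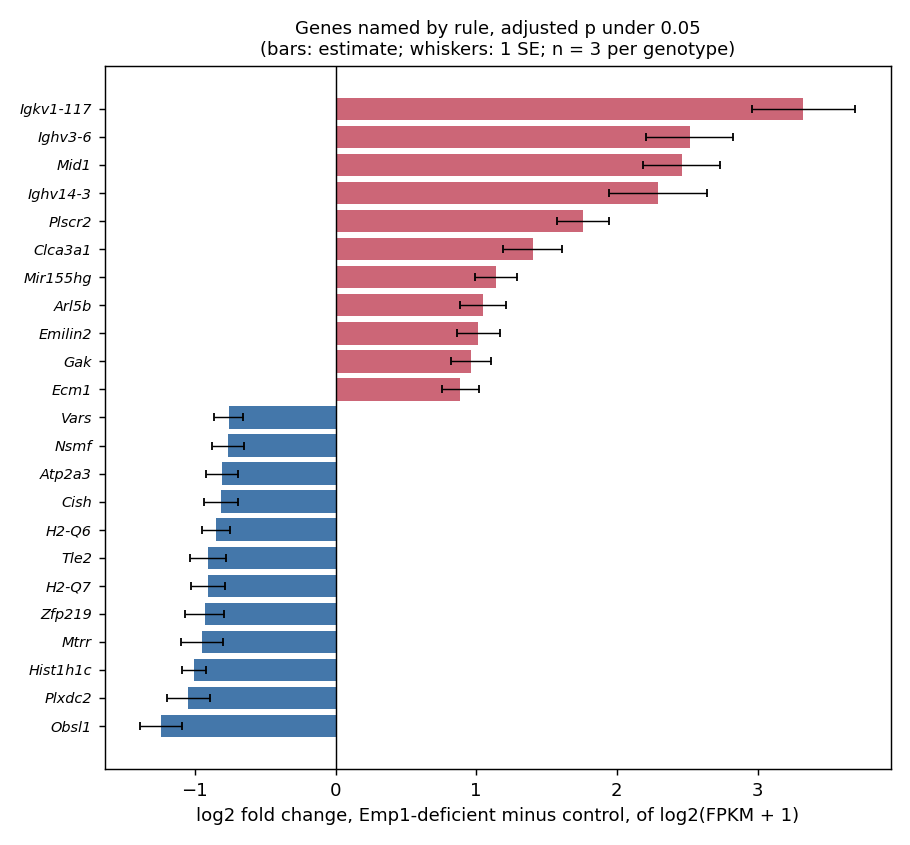
Log2 fold change on the log2(FPKM + 1) scale (horizontal axis, Emp1-deficient minus control) of the named genes that rose (red) and fell (blue); whiskers are 1 SE, n = 3 per genotype. Igkv1-110, listed at 0 in all controls, is left out; Mid1 stands at 2.46 and Obsl1 at -1.24.

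With the preset correlation of 0.01, 4 lists were higher and 3 lower. The correlation estimated for these lists ran from 0.17 (interferon response) to 0.85 (ribosomal proteins), so their preset p-values are likely too small. Other splits of the 6 libraries into 3 and 3, which mix the genotypes, called up to 17 lists against 7 here. A call alone therefore does not show an effect of genotype. Interferon response genes were lower in Emp1-deficient HSCs. Of 39 tested, 37 had a negative log2 fold change, with a median of -0.42 (camera adjusted p = 3.37e-10 with the preset correlation; adjusted p = 0.968 with an estimated correlation; fry adjusted p = 0.219). Over all genes 1 member fell, and 18 fell adjusted over the list alone. The former was Oasl2, of the oligoadenylate synthetase family, which fell from 55.1 ± 3.87 to 32.7 ± 1.52 FPKM (adjusted p = 0.0362). Without passing over all genes, Ifi44 averaged 24.5 and 12.9 FPKM, Oas2 12.8 and 7.35 FPKM, and Tap1, which encodes a subunit of the peptide transporter for class I molecules, 86.3 and 59.6 FPKM. The list stood below its 6-library mean in each Emp1-deficient library (-0.21, -0.16 and -0.29) and above it in each control.

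Genes of monocytes, macrophages and dendritic cells, mature cells that the LSK gate should remove, were lower alongside. Of 20 tested, 15 were lower, with a median of -0.58 (camera adjusted p = 0.0114; adjusted p = 0.968 with an estimated correlation). By limma 0 members fell over all genes (5 lower and 0 higher at an unadjusted p under 0.05) and 2 fell adjusted over the list alone: Irf8, a transcription factor of these lineages, from 14.4 ± 3.57 to 6.25 ± 0.792 FPKM, and Csf1r, the receptor of a macrophage growth factor, from 8.77 ± 2.55 to 3.81 ± 1.47 FPKM. Lyz2 (278 and 264 FPKM) and Cd74 (63.4 and 61.5 FPKM), abundant in such cells, differed by less than the spread between replicates. The list's level in Emp1-deficient replicate 1 was 0.27 above the 6-library mean, and -0.57 and -0.44 in replicates 2 and 3. The call was lost without Emp1-deficient replicate 2 (median -0.46, adjusted p = 0.161) and without replicate 3 (-0.46, adjusted p = 0.0523), and without replicate 1 the median was -1.03. Many members are low, and the median was -0.90 with a pseudocount of 0.1 and -0.28 with one of 5.

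All 13 mitochondrially encoded genes were higher, with a median of 0.33 (camera adjusted p = 5.12e-06; adjusted p = 0.968 with an estimated correlation). Adjusted over the list alone 8 rose, and over all genes 0 did by limma (8 at an unadjusted p under 0.05). mt-Cytb averaged 3611 ± 369 and 6537 ± 1564 FPKM, mt-Atp6 7639 ± 627 and 12600 ± 2085 FPKM, and mt-Nd2 255 ± 23.8 and 424 ± 106 FPKM. The list's level was 0.26 and 0.43 above the 6-library mean in Emp1-deficient replicates 1 and 3, but -0.094 in replicate 2, among the controls (-0.38, -0.077 and -0.14). That low level came from mt-Nd3, named after its values were seen, which stood at 62.0, 89.38 and 111.9 FPKM in controls and at 205.8, 16.09 and 183.4 FPKM in Emp1-deficient libraries (log2 fold change 0.0064). Without this gene replicate 2 stood at 0.093, and the highest control at -0.089. In 9 of the 13 genes the genotypes did not overlap. Of 78 cytosolic ribosomal protein genes 68 were lower, with a median of -0.25 (camera adjusted p = 2.45e-05; adjusted p = 0.968 with an estimated correlation). None passed by limma, over all genes or adjusted over the list alone (14 lower and 1 higher at an unadjusted p under 0.05). Rpsa averaged 653 and 482 FPKM and Rpl11 776 and 579 FPKM, whereas Rpl35 went the other way, with 935 and 1275 FPKM. Without Emp1-deficient replicate 3, the library with the lowest ribosomal protein share, the median was -0.089 and the call was lost (adjusted p = 0.0544), and without replicate 1 it was -0.38. The list of ribosome biogenesis genes, with 19 of 32 higher, was not called (adjusted p = 0.238), though it was without Emp1-deficient replicate 2 (median 0.095, adjusted p = 0.00768).

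Nuclear-encoded genes of oxidative phosphorylation were higher in 45 of 58, with a median of 0.10 (camera adjusted p = 0.00172; adjusted p = 0.968 with an estimated correlation), and proteasome subunits in 27 of 31, with a median of 0.085 (camera adjusted p = 0.00148; adjusted p = 0.968 with an estimated correlation). By limma 0 members of either list passed over all genes or adjusted over the list alone (5 higher and 2 lower, and 4 higher and 1 lower, at an unadjusted p under 0.05). Ndufa7 averaged 286 and 376 FPKM and Psmc1 121 and 151 FPKM, while Atp5b was lower at 768 and 609.7 FPKM. Both shifts leaned on Emp1-deficient replicate 1: without it the medians were 0.010 (mean -0.0083, adjusted p = 0.834) and 0.034 (adjusted p = 0.461), and without control replicate 2 that of oxidative phosphorylation was 0.062 (adjusted p = 0.145). Without Emp1-deficient replicate 2 the medians were 0.16 and 0.13, and without control replicate 1 that of the proteasome was 0.15. Quantile normalization ended both calls (adjusted p = 0.855 and 0.608), and rescaling to TPM kept them with medians of 0.051 and 0.035.

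Genes of G2 and M phase were higher in 28 of 33, with a median of 0.18 (camera adjusted p = 0.00323; adjusted p = 0.968 with an estimated correlation). By limma 0 members passed over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Ccnb1, a mitotic cyclin, averaged 38.2 ± 10.3 and 49.6 ± 8.71 FPKM, Birc5, which encodes survivin, 58.0 ± 16.4 and 72.0 ± 1.37 FPKM, and the spindle gene Tacc3 39.3 ± 6.75 and 47.6 ± 1.33 FPKM. Control replicate 1 stood 0.25 above the 6-library mean for this list, while control replicates 2 and 3 stood at -0.24 and -0.22. The call was lost without control replicate 2 (median 0.086, adjusted p = 0.390), control replicate 3 (0.0997, adjusted p = 0.0952) or Emp1-deficient replicate 2 (0.079, adjusted p = 0.0900), and without control replicate 1 the median was 0.36.

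**Figure D3:**
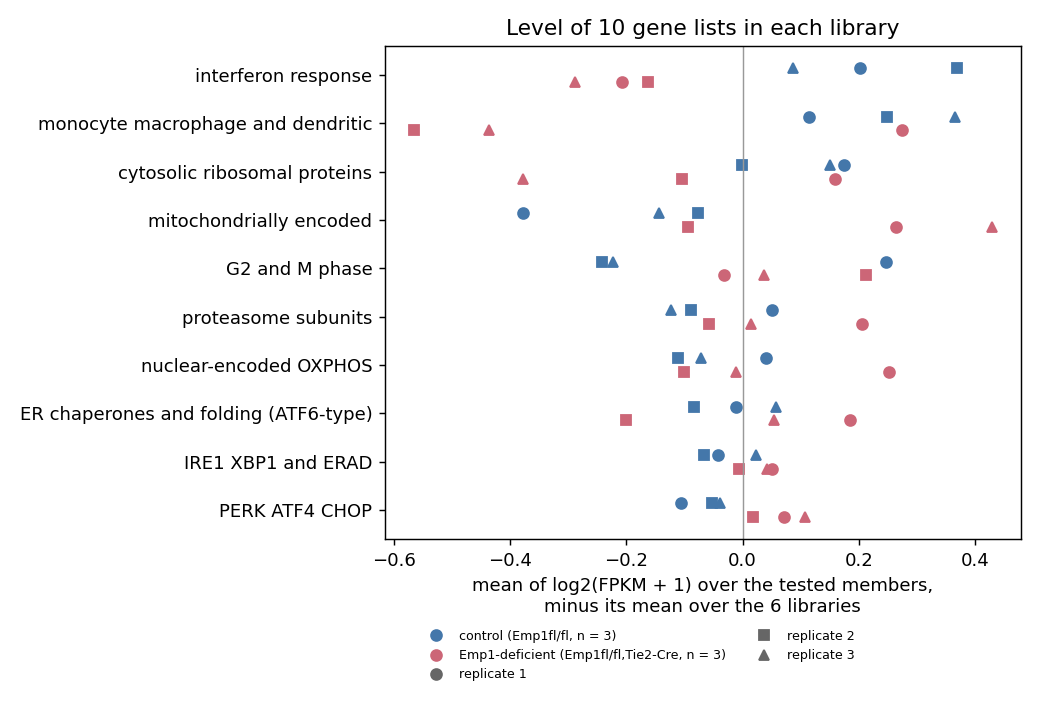
Level of 10 gene lists in each library (horizontal axis, mean of log2(FPKM + 1) over the tested members minus its mean over the 6 libraries), with controls in blue, Emp1-deficient libraries in red and a marker shape per replicate. The interferon response list separates the genotypes, while for the monocyte, macrophage and dendritic list Emp1-deficient replicate 1 (0.27) lies among the controls.

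The ER stress lists, which the series title points to, were not called in either direction. Genes of ER chaperones and folding had a median log2 fold change of 0.032 (24 tested, 13 higher, camera adjusted p = 0.452), those of the IRE1 and XBP1 branch with ER-associated degradation 0.058 (26 tested, 14 higher, adjusted p = 0.179), and those of the PERK, ATF4 and CHOP branch 0.00033 (22 tested, 11 higher, mean 0.13, adjusted p = 0.205). By limma 0 members passed over all genes (2 higher and 1 lower, 3 and 2, and 3 and 1 in the 3 lists at an unadjusted p under 0.05), and adjusted over the list alone 1 rose. That member was Herpud1, a component of ER-associated degradation, with 264 ± 26.1 and 409.5 ± 74.0 FPKM. Hspa5, the main ER chaperone BiP, averaged 559 ± 131 and 815 ± 157 FPKM, with overlapping libraries. Ddit3, which encodes the transcription factor CHOP, averaged 115 ± 7.92 and 163 ± 31.0 FPKM, but another identifier with that symbol was listed at 37.78, 10.22 and 0 FPKM in controls and at 0 in Emp1-deficient libraries. Nupr1, a stress-induced gene, averaged 30.1 ± 5.63 and 92.4 ± 44.6 FPKM, and Vldlr, Ssr1, Ero1l and Dnajb9 stood 0.60, 0.39, 0.32 and 0.23 higher on the log2 scale. The ER chaperone gene Hyou1 (10.6 and 6.69 FPKM), the stress sensor Ern1 (14.8 and 11.0 FPKM) and Atf4 (135 and 110.5 FPKM) were lower without passing. With no filter on low genes the IRE1 and PERK lists were called (adjusted p = 0.0453 and 0.0371, over alternatives from 0.0453 to 0.968 and from 0.0371 to 0.968), and without Emp1-deficient replicate 2 the chaperone list was (median 0.19, adjusted p = 0.00466). The medians of the chaperone and PERK lists turned to -0.015 and -0.039 after rescaling to TPM, and to as low as -0.043 and -0.017 with a library left out. As TPM the median over all tested genes also moved, from -0.046 to -0.0929. Relative to other genes, camera's direction for both lists stayed up there, so the TPM values are no reversal against other genes. With the GC and length trend removed, an alternative added after the data had been seen, the medians of the chaperone, IRE1 and PERK lists were higher, at 0.070, 0.11 and 0.10, without a call (adjusted p = 0.471, 0.0739 and 0.0721). The median over all tested genes was higher as well, at 0.00175 against -0.046, which accounts for a part of those rises.

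Of 25 tested p53 targets, Cdkn1a was the 1 that rose, over all genes and adjusted over the list alone, and 0 fell by limma (3 higher and 0 lower at an unadjusted p under 0.05). The list was not called (adjusted p = 0.518), and its median of -0.022 and mean of 0.030 differed in sign. Gadd45a averaged 3.95 and 7.11 FPKM and Plk2 129.9 ± 19.8 and 167 ± 4.46 FPKM, without passing. Genes of HSC quiescence were not called as a list (25 tested, 14 higher, median 0.10, adjusted p = 0.159), though without Emp1-deficient replicate 1 they were (median 0.28, adjusted p = 0.00153). Adjusted over the list alone 2 of them rose, Nr4a2 (53.9 and 82.9 FPKM) and Jund (12.6 and 19.2 FPKM), and 1 fell, the endothelial and stem cell receptor Tie1 (36.8 and 22.8 FPKM). Over all genes 0 passed by limma (6 higher and 4 lower at an unadjusted p under 0.05), and the cell cycle inhibitor Cdkn2c stood 0.69 higher. Genes of HSC identity had 23 of 31 lower, with a median of -0.13 (adjusted p = 0.214), and 0 passed by limma over all genes or adjusted over the list alone (2 higher and 4 lower at an unadjusted p under 0.05). That median leaned on Emp1-deficient replicate 1, whose level was -0.39 against the 6-library mean, while replicates 2 and 3 (0.041 and 0.11) lay among the controls (0.16, 0.17 and -0.088). Without it the median was -0.017 (adjusted p = 0.911), whereas without control replicate 3 (-0.22, adjusted p = 0.0390) or Emp1-deficient replicate 3 (-0.26, adjusted p = 0.00150) the list was called. The stem cell transcription factors Prdm16 (23.2 and 14.8 FPKM) and Hlf (57.9 and 39.8 FPKM) and the surface gene Ly6a, which encodes Sca-1 (93.1 and 73.6 FPKM), were lower, while the integrin gene Itga6 was higher (35.4 and 44.9 FPKM). In all, 28 of the 35 lists were not called (adjusted p from 0.0612 to 0.991), and among these the signs of median, mean and test differed in 11.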

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

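The GC and length correction and the restriction to long protein-coding genes were chosen after the data had been seen, and all other alternatives before. Higher and lower genes (25 and 17) became 14 and 15 with a pseudocount of 0.1, 6 and 9 with one of 5, 2 and 3 with no filter, 46 and 58 with a mean of at least 5 FPKM, 15 and 9 with median-ratio scaling and also with quantile normalization, 11 and 13 as TPM, 5 and 3 without trend and robustness, 37 and 45 with array weights, 15 and 5 with the GC and length trend removed, and 70 and 142 among protein-coding genes of at least 400 bp. Leaving out a library gave 1 to 12 higher and 0 to 16 lower. Part of the change has its cause in the number of genes or samples tested. Another part lies in how limma sets the variance, since the fit without trend and robustness used the same genes and libraries. Among protein-coding genes of at least 400 bp Emp1 kept its log2 fold change of -1.53, yet its unadjusted limma p went from 0.00018 to 4.45e-05. Otherwise the cause was not tested. With the replicate block, 6 genes were higher and 2 lower. There was no clear sign that shared replicate numbers paired the samples: the deviations of same-numbered libraries correlated at -0.108, 0.086 and -0.052, and not every library correlated best with its own number. Deviations from a mean of 3 libraries are tied to each other, so these values cannot exclude a shared litter or day of the sort. The 4 higher lists became 8 with no filter, 2 with quantile normalization and 2 to 8 with a library left out, and the 3 lower lists 2 to 4 with a library left out.

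With an estimated correlation, and by fry, 0 lists were higher and 0 lower, with the medians as before: -0.42 for interferon response, 0.33 for mitochondrially encoded genes, -0.25 for ribosomal proteins, 0.085 for the proteasome, 0.10 for oxidative phosphorylation, 0.18 for G2 and M phase and -0.58 for monocytes, macrophages and dendritic cells. The camera adjusted p of 0.968 with an estimated correlation is shared by all 7 called lists, so it does not rank them. The estimated correlation was 0.17 for interferon response, 0.31 for monocytes, macrophages and dendritic cells and 0.62 for mitochondrially encoded genes. It was 0.64 for oxidative phosphorylation, 0.65 for the proteasome, 0.72 for G2 and M phase and 0.85 for ribosomal proteins. The unadjusted camera p ran from 0.0412 for interferon response to 0.493 for oxidative phosphorylation, and the unadjusted fry p for these lists was 0.00627 and 0.478. Quantile normalization ended the calls of the proteasome (0.026) and oxidative phosphorylation (0.028), and TPM kept them at 0.035 and 0.051. Leave-one-out medians ran from -0.38 to -0.089 for ribosomal proteins, 0.034 to 0.15 for the proteasome, 0.079 to 0.36 for G2 and M phase, 0.010 to 0.16 for oxidative phosphorylation, and -1.03 to -0.46 for monocytes, macrophages and dendritic cells. The interferon and mitochondrially encoded lists kept their calls in every leave-one-out fit (-0.50 to -0.34, and 0.26 to 0.46). The PERK list turned negative with a pseudocount of 5 (-0.016), a mean of at least 5 FPKM (-0.051), TPM (-0.039) and array weights (-0.0037), and ran from -0.017 to 0.075 with a library left out. It was called with no filter (0.045), as was the IRE1 list (0.058), which otherwise stood at 0.098 with a mean of at least 5 FPKM, 0.0091 as TPM, 0.11 with the GC and length trend removed and 0.027 to 0.074 with a library left out. The chaperone list turned negative as TPM (-0.015) and ran from -0.043 to 0.19 with a library left out. The median over all tested genes moved with the setting too, from -0.046 in the main fit to -0.0929 as TPM. Lists not called in the main analysis were called with some library left out: chaperones, MYC targets, ribosome biogenesis, S phase and cholesterol without Emp1-deficient replicate 2, HSC quiescence and immediate early genes without replicate 1, HSC identity without replicate 3, S phase and cholesterol without control replicate 1, and HSC identity, cholesterol and immediate early genes without control replicate 3. The median of HSC identity ran from -0.26 to -0.017 in these fits. The cause was not tested. Emp1 passed with array weights (-1.52) and among long protein-coding genes (-1.53), and ran from -1.66 to -1.39 with a library left out (adjusted p from 0.0717 to 0.203).

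Of single genes named, 5 near 0 changed sign. Emp2 (main value -0.0017) stood at 0.012 with a pseudocount of 0.1, 0.013 with median-ratio scaling, 0.094 with quantile normalization, 0.083 with the GC and length trend removed, 0.062, 0.089 and 0.11 without control replicates 2 and 3 and Emp1-deficient replicate 3, and ran from -0.16 to 0.11 with a library left out. Emp3 stood at -0.055 with quantile normalization, -0.0098 as TPM and -0.011 without control replicate 2 (-0.011 to 0.13 with a library left out). Pmp22 stood at 0.0096 with quantile normalization and 0.00076 without Emp1-deficient replicate 3 (-0.26 to 0.00076 with a library left out). Cd74 stood at 0.029 with the GC and length trend removed, and at 0.18 without control replicate 2 or Emp1-deficient replicate 2 (-0.37 to 0.18 with a library left out). The mitochondrially encoded mt-Nd3 (main value 0.0064) stood at -0.0084 with a pseudocount of 0.1, -0.080 with quantile normalization, -0.048 as TPM, -0.18 with array weights, -0.087 with the GC and length trend removed, and -0.22, -0.62 and -0.54 without control replicate 1 and Emp1-deficient replicates 1 and 3 (-0.62 to 1.18 with a library left out). In the other values of single genes, 1530 kept direction and side of the threshold, 315 lost the call and 26 gained it. The 1530 include values of genes not called in the main analysis, which cannot lose a call, so they do not measure how stable the calls are. The 24 named genes that passed kept their calls in between 2 of 13 alternatives (Ighv14-3) and 16 of 18 (Hist1h1c). Absolute depth is unknown, so values near 0 cannot be given a detection limit.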

Other observations

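The tests of the interferon genes adjusted for myeloid level and of GC content over the called genes, and the count of neighbouring genes without pairs that overlap each other, were chosen only after the results had been seen. Among markers of other cell types, most of which the LSK gate should remove, 0 passed over all genes by limma, and the counts that follow are adjusted over the list alone. Of 11 tested genes of T and NK cells 2 rose and 3 fell (2 higher and 3 lower at an unadjusted p under 0.05): Cd4 averaged 4.78 ± 1.57 and 0.93 ± 0.316 FPKM in control and Emp1-deficient HSCs, and the T-cell receptor constant regions Trbc2 and Trbc1 2.53 ± 1.16 and 0.273 ± 0.208 FPKM, and 8.44 ± 5.34 and 1.11 ± 1.27 FPKM. The 2 that rose, Nkg7 and Gzmb, which encode proteins of cytotoxic granules, averaged 217 ± 36.8 and 313 ± 55.3 FPKM, and 2.13 ± 1.27 and 6.23 ± 2.11 FPKM. Trbc1, Gzmb, Plek and Selp are named because they complete these counts, after their values were seen. The list's median of 0.14 and mean of -0.26 differed in sign. Of 20 megakaryocyte and platelet genes, 15 of them lower, 3 rose and 1 fell (3 and 1 at an unadjusted p under 0.05), with the von Willebrand factor receptor gene Gp1ba at 8.84 and 16.9 FPKM, Plek at 92.5 and 127 FPKM, Selp at 47.6 and 112.5 FPKM and the platelet receptor gene Treml1 at 22.0 and 14.9 FPKM. The median of that list was -0.050, with no call (camera adjusted p = 0.9905). Of 16 endothelial genes 2 fell (0 higher and 3 lower at an unadjusted p under 0.05), Tie1 and the co-receptor gene Eng (119.5 ± 1.96 and 86.5 ± 2.86 FPKM), both of which HSCs also express. Of 8 basophil and mast cell genes 2 rose and 1 fell (2 and 1 at an unadjusted p under 0.05), namely Fcer1a, a subunit of the IgE receptor, at 19.4 ± 7.90 and 48.3 ± 7.13 FPKM, Gzmb, and the cytokine gene Il4 at 12.95 ± 1.92 and 7.68 ± 2.26 FPKM. Of 14 genes of lymphoid-primed multipotent progenitors, 9 of them lower, 1 rose and 0 fell (1 higher and 2 lower at an unadjusted p under 0.05), with a median of -0.16 and no call (adjusted p = 0.585). That gene was Cd53, a tetraspanin of leukocytes, at 66.0 ± 14.8 and 115 ± 6.52 FPKM, while Satb1, a chromatin organizer of lymphoid cells, averaged 12.6 ± 4.22 and 6.93 ± 1.73 FPKM without passing. Of 7 stromal and osteolineage genes, 5 of them lower, 1 rose and 0 fell (1 and 0 at an unadjusted p under 0.05), namely Spp1, which encodes osteopontin, from 4.58 ± 1.04 to 9.82 ± 2.14 FPKM. The median of that list, -0.11, and its mean, 0.015, differed in sign.

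Of 27 genes of glycolysis and hypoxia, 1 rose and 1 fell adjusted over the list alone and 0 over all genes by limma (2 higher and 3 lower at an unadjusted p under 0.05): Hk2, which encodes a hexokinase, at 47.6 ± 7.70 and 71.9 ± 5.68 FPKM, and P4ha1, a subunit of collagen prolyl hydroxylase, at 10.8 ± 0.911 and 5.70 ± 0.965 FPKM. Of 23 NF-kB and inflammatory genes 1 rose and 2 fell adjusted over the list alone and 0 passed over all genes (3 higher and 4 lower at an unadjusted p under 0.05), with the NF-kB subunit gene Rel at 20.2 ± 2.54 and 30.8 ± 2.39 FPKM, Gadd45b at 50.8 ± 7.39 and 36.2 ± 3.78 FPKM and Tnfaip2 at 15.3 ± 0.842 and 9.54 ± 2.64 FPKM. Hmox1, which encodes the haem-degrading enzyme, averaged 32.1 ± 8.21 and 10.8 ± 6.96 FPKM and did not pass, over all genes or adjusted over the antioxidant list alone, where 0 of 27 members did (0 higher and 4 lower at an unadjusted p under 0.05).

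Both the single library with the lowest ribosomal protein share and the GC and length trend were set out as sources of the mitochondrially encoded and ribosomal protein shifts, and the choice to give these 4 tests as values alone was made after their results had been seen. The mitochondrially encoded list had a median of 0.26 without Emp1-deficient replicate 3 and of 0.24 with the trend removed, with the call kept in each. The cytosolic ribosomal protein list had a median of -0.089 without that library, with the call lost (adjusted p = 0.0544), and of -0.19 with the trend removed, with the call kept.

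The lower level of interferon response genes could reflect fewer myeloid cells, although the LSK gate should remove these from all libraries, a trend with GC content between libraries, or the genotype. After adjustment for the monocyte, macrophage and dendritic level over the 6 libraries the genotype difference was -0.452, against -0.438 unadjusted. Its 95% interval (-0.893 to -0.0101, 3 residual degrees of freedom) only just excluded 0, which met the prediction written for another cause than fewer myeloid cells. The fitted slope on the myeloid level was -0.0277. Many members of that list are low, and noise in its level would pull the slope toward 0. The adjusted difference would then stay near the unadjusted one in either case, so the adjustment cannot decide. With each library's GC and length trend removed the list's median was -0.334, against -0.422 before, with the call kept. This argues against that trend as the whole cause, while a part in the shift is not excluded. The 10 splits of 6 libraries cannot give a share under 0.1: the size of the real median was 0.422 and the highest other 0.319, and the unadjusted camera p, on which the test had been set out, was 9.64e-12 in the real split and as small as 1.87e-07 in a split that mixes the genotypes. The genotype therefore stays open as the cause, as do fewer myeloid cells and differences between mice, litters or days of the sort. Neither the genotype nor such differences were tested. Genotype here covers both loss of Emp1 and the Tie2-Cre transgene, since no sample carried Tie2-Cre without floxed Emp1 alleles.

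Higher immunoglobulin V segments in Emp1-deficient libraries could come from RNA of antibody-secreting cells, which the LSK gate should remove, or from the chance capture of a few abundant clones. The summed FPKM of all 218 annotated V segments was 127, 557 and 878 in controls and 2610, 409 and 1572 in Emp1-deficient libraries, a ratio of means of 2.94 with overlapping genotypes, while the segments at 1 FPKM or more numbered 34, 40 and 56 and 90, 80 and 80. Other genes of such cells, chosen after their values were seen, went both ways: the constant genes Ighg2b and Ighg2c were higher in each Emp1-deficient library, whereas Sdc1, which encodes the plasma cell surface protein syndecan-1, was lower in each (2.07, 2.59 and 2.61 against 5.03, 11.58 and 3.85 FPKM). Jchain, which encodes the joining chain of secreted antibodies, overlapped (2.72, 25.75 and 6.61 FPKM in controls, 21.55, 9.22 and 14.66 FPKM in Emp1-deficient libraries), as did Igkc, and none of these genes passed the test over all genes. Ighm, Ighg1, Igha, Mzb1, Tnfrsf17, Prdm1, Xbp1, Derl3 and Txndc5 overlapped as well, so most of the genes looked at did not separate the genotypes. The source of the segments therefore stays open, and a change in the HSCs themselves was not tested.

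The genes called between the genotypes could follow from GC trends, from linked differences between the mice, from loss of Emp1, or from the Tie2-Cre transgene itself. No sample carried Tie2-Cre without floxed Emp1 alleles, so loss of Emp1 and the transgene cannot be told apart here. Nor can loss of Emp1 in HSCs be told apart from its loss in endothelial cells, where Tie2 is also active. With the GC and length trend removed, the median ratio of the log2 fold change after over before was 0.98 (lower quartile 0.896), which argues against the trend as the whole cause of the folds, yet calls were lost in both directions and why was not tested: of the genes above 0 in both genotypes, 10 of 19 higher genes stayed called with a median going from 1.05 (SE 0.152) to 1.07 (SE 0.16), and 3 of 15 lower genes, whose median GC content was 56.7% against 49.5% of tested genes, with one going from -0.907 (SE 0.121) to -0.697 (SE 0.122). Outside gene families 5 pairs of called genes lay within 1 Mb (1.37 by chance, permutation p = 0.0189 from 10000 random draws), which meets the prediction written for linked differences. Without pairs whose members overlap each other 3 pairs were left (permutation p = 0.147). All 5 pairs lie in the regions of Vars or Mid1, so they are not independent and neither p decides the question. Vars lies near H2-Q6 and H2-Q7, near-identical copies that may share reads. G530011O06Rik (0.45 and 4.02 FPKM) and Gm15247 (0.187 and 7.10 FPKM), named after their values were seen, lie within Mid1, at the pseudoautosomal boundary, and rose with it. Their pair is among the 3, although both overlap Mid1. Linked differences therefore stay open. The 10 splits cannot give a share under 0.1: 42 genes were called in the real split and 10 in the highest other. For lists the real split called 7, the highest other 17, and 7 of the 10 splits called as many, so sets of co-varying genes were called in splits that mix the genotypes.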
